A study of Drosophila melanogaster with 4 samples.

How the data were processed

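The study comprised 2 ChIP libraries, made with an antibody to CG8478, and 2 input libraries, all from S2-DRSC cells. Per the labels' protocols, cells were fixed with 1.8% formaldehyde for 15 minutes and the chromatin was sonicated. Groups and replicate numbers were taken from the sample titles. The processed data were 1 peak list for the whole series. The source column of the list names MACS as the peak caller, and per the file headers its positions are on FlyBase release 5. CASAVA (1.7.0.2 and 1.7.0.3), BWA, MACS2 and the build BDGP5 are named in the submitters' processing notes, without roles or parameters. The threshold of the peak calls, the use of the input libraries as control and whether replicates were pooled before calling are not given in the sources used here.

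The score of each peak was used as deposited by the authors. The sources do not say which statistic of the caller it is, so the report uses it only to describe, rank and compare peaks within this list. The closing part also reads it, as a hypothesis, as the negative log10 of a Poisson p-value, and what is said there of backgrounds rests on that reading. Start and end were read as 1-based inclusive positions. The peaks are numbered 1 to 3284 in file order without a gap, no pair overlaps, and the smallest gap between neighbours is 50 bp. A call that depends on how enrichment is split into peaks changes the number of peaks and their spacing, so merged lists were tried as alternatives. Because the list holds no reads, depth, coverage and replicate error could not be computed. Intervals on shares (Wilson, 95%) and densities (exact Poisson, 95%) cover counting error only.

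The peaks were compared by chromosome, by spacing and by location, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The comparison of X with the autosomes, the spacing test and the rule for named peaks (the 25 of highest score) were set before the data were examined. The gene table used for names is of Release 6, another build than that of the peaks, and no genome sequence was used. The planned comparisons with start sites, annotation classes, gene lists, divergent promoters, motifs and 7-mers were therefore not run, and no gene is named for a peak. For this case the plan set that no arm lengths be used and that X be described by counts alone. The densities and the binomial test of X on the span from the first to the last peak of each arm depart from that plan. They and the comparisons by 1 Mb windows, clusters, scores and widths were added after the list had been seen.

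For spacing and clusters, peak midpoints on the arms X, 2L, 2R, 3L, 3R and 4 were placed at random 1000 times between the first start and last end of each arm, and the p-value was 2 times the smaller tail. Placements may fall in sequence to which reads do not align, and they may overlap. A cluster joined peaks with at most 10 kb between them, and a large cluster had at least 5 peaks. Windows of 1 Mb that ended before the last peak of an arm were compared between each arm and all others by permuting windows (100000 resamples, two-sided, Benjamini-Hochberg over 5 arms). Scores and widths were compared by permuting peaks (difference of medians, 100000 resamples, two-sided, Benjamini-Hochberg over 8 tests). Peaks and windows are not replicates of the experiment, and neighbouring ones are not independent.

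The tests were tried on simulated data, with fewer placements and resamples per list than in the analysis. Of 50 simulated lists of 2938 unclustered peaks, 2 were called clustered by spacing and 2 by large clusters, and all 50 lists with 1 in 5 peaks moved beside another were called by spacing. In 400 simulated sets of 117 windows, 19 were called with no difference on X and 388 with a 2-fold density on X. A first run of 50 such sets had given a larger share of false calls, which is why the number was raised to 400, with the test unchanged. No difference smaller than 2-fold was simulated for windows, so the power of that test for smaller differences is unknown. The simulated window counts also spread less around their mean than the observed counts, so the share called at 2-fold may be too high. Of 50 simulated sets of 2938 scores, 1 was called with no difference and 50 with a 1.5-fold difference. The simulated scores were shuffled and the simulated windows drawn independently. The share of false calls where neighbouring peaks or windows depend on each other is therefore unknown. The fit of the score ladder, described in the closing part, gave back a simulated background of 40. The alternatives were a list restricted to the 1642 highest-scoring peaks, lists merged at an overlap of 1 bp or within 200 or 1000 bp, other window and cluster sizes, random placement within windows, and mean log2 values in place of medians.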

Results

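Binding of the protein CG8478 to the genome was mapped by ChIP-seq in S2-DRSC cells, a male Drosophila melanogaster line of late embryonic origin. In this assay, formaldehyde-fixed chromatin is sheared and precipitated with an antibody, and the recovered DNA is sequenced beside unprecipitated input DNA. The antibody was a rabbit polyclonal raised against a fragment of CG8478 whose sequence, as given in the labels, carries a C2H2-type zinc finger, a fold found in many DNA-binding proteins. The series holds 2 ChIP libraries and 2 input libraries. The values analysed were those of 1 peak list for the whole series, with a position and a score for each peak and no value per library. Read depth per library was therefore unknown here, no replicate error could be given, and no p-value below measures the spread between libraries. All coordinates are 1-based positions on FlyBase release 5, the build in the file header.

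The first question was how many peaks were called and what scores and widths they had. Whether each call marks a region bound by the protein was not tested. The list held 3284 peaks that covered 1.83 Mb. The median width was 396 bp, and the 5th and 95th percentiles were 207 and 1424 bp. The narrowest peaks were 201 bp, a width shared by 80 peaks, and the widest was 5423 bp. The median of the authors' score was 14.3, with quartiles of 10.5 and 24.7 and a range from 5.64 to 304. A score of 100 or more was reached by 92 peaks, 2.80% of the list. Higher-scoring peaks were wider, and a strong peak below means only one with a high score. The 328 highest-scoring peaks had a median width of 984.5 bp, against 247 bp for the 328 lowest. Across all peaks Spearman's rho of width and score was 0.71. It was 0.75 on the chromosome arms, 0.58 on unplaced and heterochromatic scaffolds and 0.71 for the mitochondrial genome. These are correlations across peaks, which are not independent replicates, and no p-value is attached to them.

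**Figure D1:**
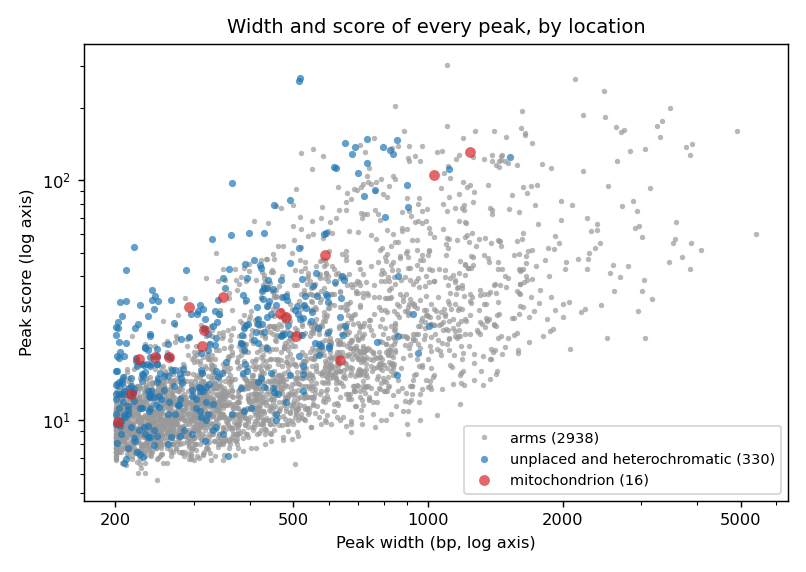
Width in bp (x, log axis) against the authors' peak score (y, log axis) for all 3284 peaks, 1 point per peak, with 2938 peaks on the chromosome arms in grey, 330 on unplaced and heterochromatic scaffolds in blue and 16 on the mitochondrial genome in red. Score and width increase together, and the median width is 318 bp for scaffold peaks and 411 bp for arm peaks.

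The 25 highest-scoring peaks, chosen by a rule fixed before the data were examined, had scores from 151 to 304 and a median width of 1652 bp. Of these, 8 lay on X, 6 on 2R, 5 on 3R, 3 on 3L, 1 on 2L, and 1 each on the unplaced sequence collections U and Uextra. The strongest peak of the list spanned 3L 377662 to 378766, with a score of 304 and a width of 1105 bp, and no other peak lay within 10 kb of it. The strongest X peak spanned 9586470 to 9588597, with a score of 266. A group of 3 further X peaks in this set lay close together: 12557189 to 12560668 (score 201), 12628015 to 12630762 (score 163) and 12645228 to 12648483 (score 169). The strongest peak on 2R spanned 9844162 to 9846633 (score 237), that on 2L spanned 1643480 to 1645101 (score 194), and that on 3R spanned 25598297 to 25600783 (score 185). The peaks ranked 2 and 4 in the whole list were the ones on U, at 2605829 to 2606347 (score 268), and on Uextra, at 22939324 to 22939839 (score 260). They were nearly equal in width, at 519 and 516 bp. Genes at these positions were not analysed here, because no annotation of the build of the peaks was used.

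The labels give the cell line as male, so X was compared with the autosomes. The 6 arms X, 2L, 2R, 3L, 3R and 4 together held 2938 peaks, 89.5% of the list, and X held 461 of them, 15.7% (Wilson 95% interval 14.4 to 17.1%). Taken over the length between the first and last peak of each arm, X had 21.2 peaks per Mb (exact Poisson 95% interval 19.3 to 23.2) and the autosomal arms had 25.6 (24.6 to 26.6), a ratio of 0.83. An exact binomial test (two-sided) of the peak count on X against its 18.4% share of this length gave p = 0.000137. The plan was to give counts alone where no arm lengths of this build were used, so this density comparison departs from the plan and was added after the data were seen. The binomial test treats every peak as independent, and the intervals cover counting error only. Neither takes account of the copy number of X and the autosomes in this male line, which was not measured in the values used here. Peaks were clustered along the arms, as described next, so the arms were also compared by windows of 1 Mb. X had 20.8 ± 23.2 peaks per window (SD, 22 windows) and the other arms had 25.4 ± 20.6 (SD, 95 windows). The difference did not pass the permutation test over windows (100000 resamples, two-sided, p = 0.36, adjusted p = 0.50 over 5 arms). Power for a difference of this size was not simulated, so a small difference on X is not excluded. The scores of X and autosomal peaks did not differ beyond the same kind of test either, with medians of 14.3 and 13.6 (permutation test of the difference of 0.66, adjusted p = 0.24), nor did their widths, with medians of 390 and 413 bp (adjusted p = 0.25).

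Among the autosomal arms, 2R had the highest density and 2L the lowest. The arm 2R held 744 peaks, or 35.3 ± 22.5 per 1 Mb window (SD, 21 windows), against 22.2 ± 20.2 on all other arms (SD, 96 windows). This excess of 13.1 peaks per window passed the permutation test at adjusted p = 0.044. It did not pass among the 1642 highest-scoring peaks, where the excess was 4.50 peaks per window (permutation test, adjusted p = 0.24). The arm 2L held 383 peaks, or 16.9 ± 15.6 per window (SD, 22 windows), against 26.3 ± 21.9 on the others, with an adjusted p of 0.14. By the same permutation test, mean counts of 23.0 per window on 3L (adjusted p = 0.68) and 27.6 on 3R (adjusted p = 0.50) did not differ from the other arms beyond the threshold. The small chromosome 4 held 27 peaks between 340820 and 1320332. Its 1 whole window, with 5 peaks, was too few for a test of its own and was counted among the other arms in each test above. Copy number of the arms in this line was not measured in the values used here.

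**Figure D2:**
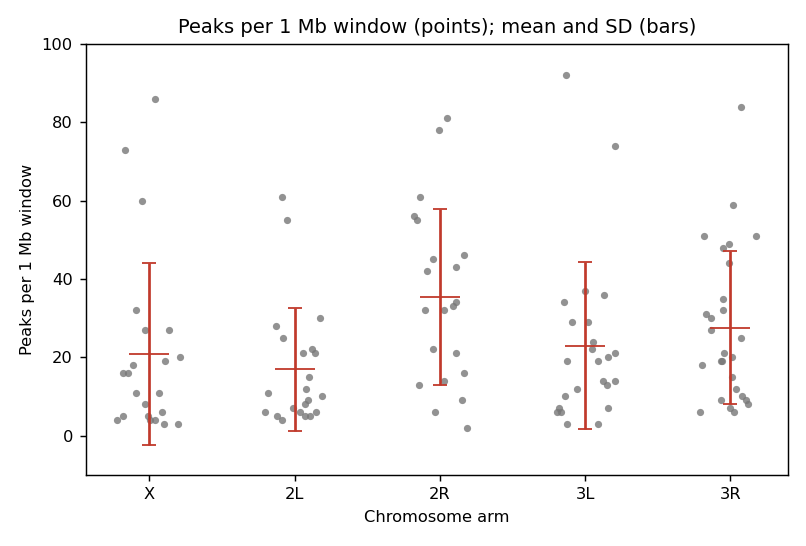
Number of peaks in each 1 Mb window (y) for the arms X, 2L, 2R, 3L and 3R (x), 1 grey point per window, with red bars for the mean and SD over windows. The means run from 16.9 on 2L to 35.3 on 2R, and single windows reach 92 peaks on 3L and 86 on X.

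Peaks were not spread evenly. Over the 117 whole windows of 1 Mb the count averaged 24.5 with an SD of 21.1, and the variance was 18.1 times the mean, where independent placement would give a ratio near 1. No window was empty. The 11 fullest windows, with at least 59 peaks each, held 28.2% of the 2872 peaks in the 117 windows. The fullest were the first Mb of 3L with 92 peaks, the window from 3 to 4 Mb on X with 86, that from 5 to 6 Mb on 3R with 84, and those from 14 to 15 Mb and 6 to 7 Mb on 2R with 81 and 78. The median distance between neighbouring peak midpoints on the arms was 4083.5 bp. In 1000 random placements of the same number of peaks between the first and last peak of each arm, the median averaged 26949 bp and never fell below 25462 bp (two-sided permutation p = 0.002, the smallest these placements can give), a ratio of 6.60 to the observed median. The ratio was 4.67 with each peak placed within its own 1 Mb window and 2.47 within its own 100 kb window, where the random mean was 10070 bp. Of neighbouring pairs, 20.4% lay within 1 kb of each other and 62.6% within 10 kb, against means of 2.60% and 22.9% in the random placements.

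**Figure D3:**
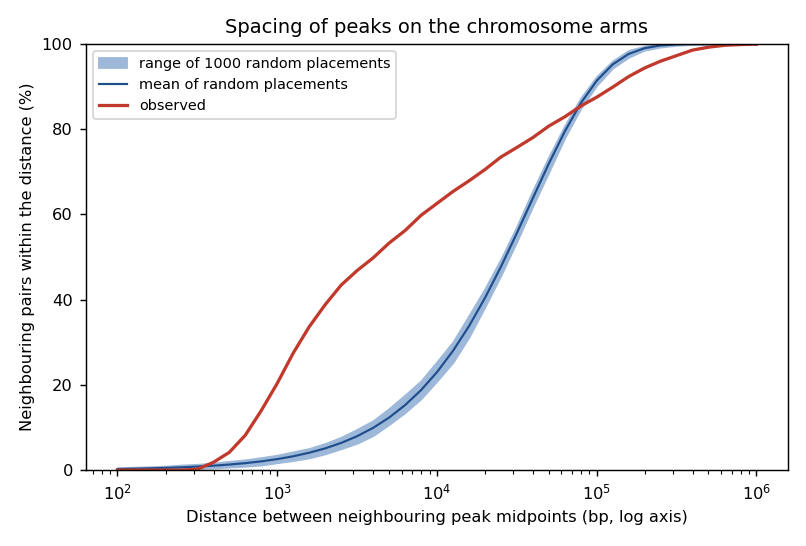
Percentage of neighbouring peak pairs on the arms (y) whose midpoints lie within a given distance in bp (x, log axis), observed (red) and in 1000 random placements (blue line, mean, and band, range). The observed curve passes 20.4% at 1 kb and 62.6% at 10 kb, where the random mean of the placements drawn here is 2.58% and 23.0%.

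To name the crowded regions, peaks with at most 10 kb between them were joined into chains, and a chain of 5 or more peaks was called a large cluster. The arms held 141 large clusters with 1449 peaks, 49.3% of arm peaks, against a mean of 1.63% and a maximum of 3.54% in the random placements (two-sided permutation p = 0.002). With each peak placed within its own 1 Mb window, the random mean was 9.22%, so the excess depends on the reference. Single peaks with no neighbour within 10 kb made up 19.8% of arm peaks. The median large cluster spanned 18.6 kb. The share of an arm's peaks in large clusters was 59.3% on chromosome 4 (16 of 27 peaks, Wilson 95% interval 40.7 to 75.5%), 57.5% on X (52.9 to 61.9%), 52.8% on 2R (49.2 to 56.4%), 50.7% on 3L (46.6 to 54.9%), 44.3% on 3R (40.8 to 47.9%) and 39.9% on 2L (35.2 to 44.9%). Differences between these shares were not tested, and peaks of 1 cluster are not independent. A total of 16 arm clusters had 20 or more peaks. The largest spanned 3L 3374172 to 3461861, with 37 peaks in 87.7 kb. It was followed by 2R 7480531 to 7553249 with 34 peaks, 3R 11798805 to 11877526 with 31, and 2R 6952864 to 7007210 with 29. On X the largest were 3565945 to 3598656 with 24 peaks and 3237853 to 3303204 with 23, and on 2L it was 472217 to 506665 with 21. Chromosome 4 had 1 large cluster, of 16 peaks, between 1264009 and 1277830.

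**Figure D4:**
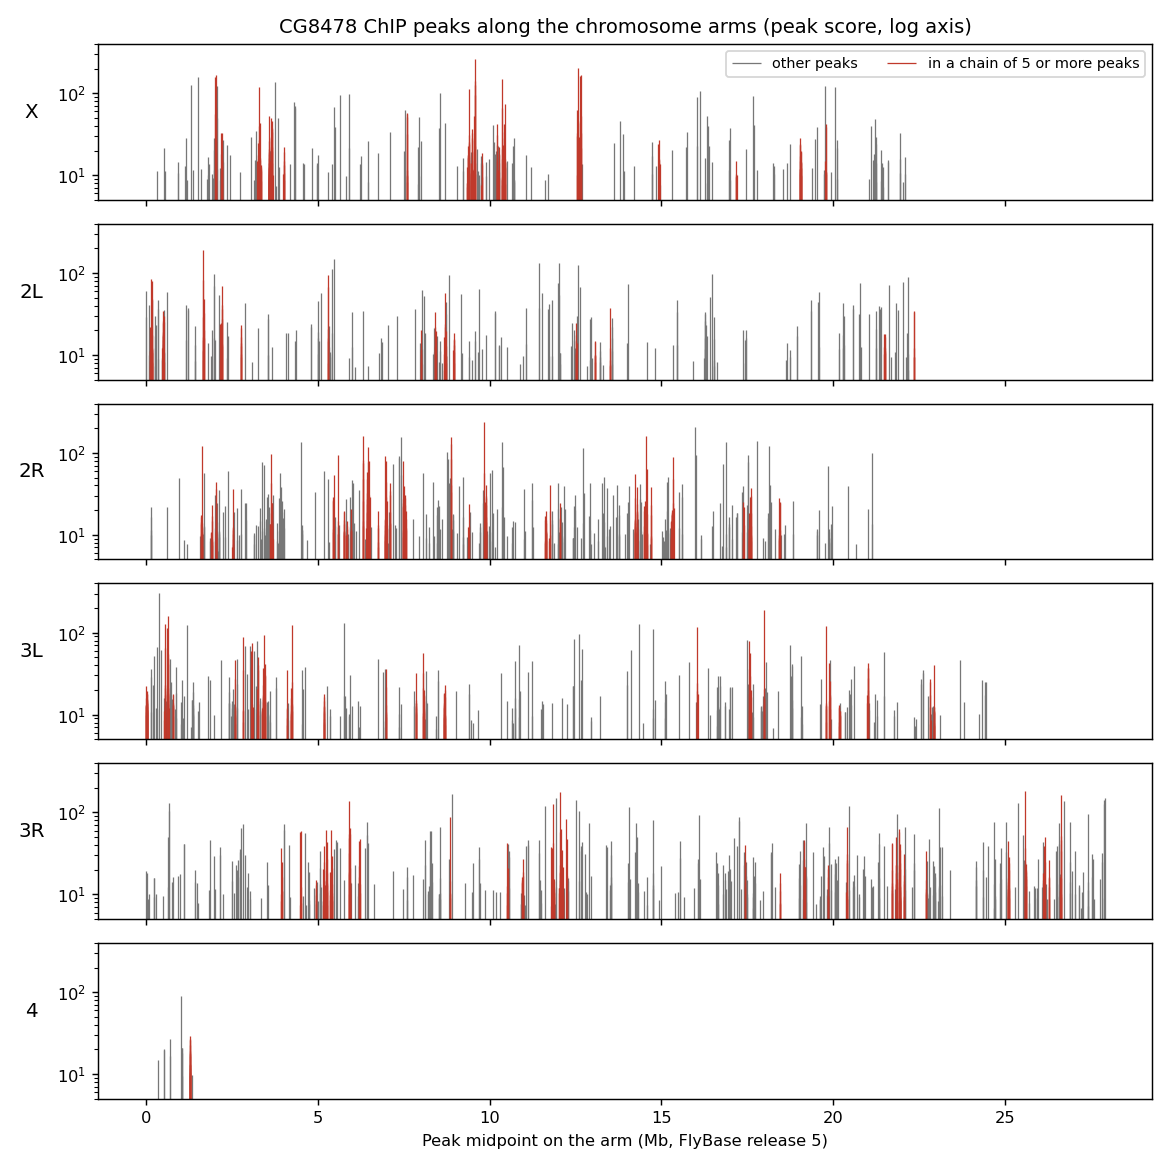
Each vertical line is 1 peak at its midpoint on the arm (x, Mb, FlyBase release 5) and reaches the authors' score (y, log axis from 5), for the arms X, 2L, 2R, 3L, 3R and 4 from top to bottom. Red lines are the 1449 peaks in chains of 5 or more peaks with at most 10 kb between neighbours, and grey lines are the other arm peaks.

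Peaks in large clusters scored lower than isolated peaks. Their median score was 13.03 (quartiles 10.2 and 20.1, 1449 peaks), against 15.9 (11.3 and 32.9, 583 peaks) for peaks alone in their chain. The difference of -2.89 passed the permutation test (100000 resamples, two-sided, p = 1e-05, the smallest these resamples can give, adjusted p = 4.0e-05 over 8 tests). Widths were 397 and 430 bp in the median, a difference that did not pass (permutation test, adjusted p = 0.14). A high score within a cluster was nevertheless common at the top of the list, since 17 of the 25 strongest peaks lay in large clusters. The tests of score and width shuffled single peaks, and neighbouring peaks of a cluster are not independent. Whether a higher local background at the clusters, taken up in the closing part, lowered their scores was not tested.

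Peaks lay close to the first base of 2L, 3L and 3R. No arm lengths were used, so the distance of a last peak from the end of its arm is unknown here. On 2L the first peaks spanned 137 to 606 (score 28.8) and 672 to 6094 (score 60.0), and the latter, at 5423 bp, was the widest of the list. On 3R the last 3 peaks ran almost without a break from 27898914 to 27905038, with scores of 142, 126 and 150. The last peak on 2R spanned 21145749 to 21146533 and scored 101. At the start of 3L, 25 peaks between positions 673 and 19658 covered 73.4% of that stretch, with scores from 9.99 to 22.1 only, and the next peak began at 128133. On 3R the first peak spanned 123 to 727 (score 19.2). The first peaks on 2R, X and 4 lay farther in, at 148356, 328072 and 340820.

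Outside the arms, 330 peaks (10.0%, Wilson 95% interval 9.07 to 11.1%) lay on unplaced and heterochromatic scaffolds. Uextra held 227 and U held 68, and the scaffolds assigned to heterochromatin held 35, of which 4 lay on YHet between 71738 and 76338. Peaks on these scaffolds were narrower and scored higher than arm peaks. Their median width was 318 bp against 411 bp (difference -93.0 bp, adjusted p = 5.3e-05) and their median score 19.2 against 13.9 (difference 5.31, adjusted p = 4.0e-05, both by permutation test). The mitochondrial genome held 16 peaks between positions 20 and 18771. Their median score was 23.2 (quartiles 18.3 and 30.5), which exceeded that of arm peaks by 9.28 (permutation test, adjusted p = 0.034). With peaks within 200 bp merged, the difference was 9.50 and did not pass (permutation test, adjusted p = 0.084). The strongest mitochondrial peaks spanned 13693 to 14933 (score 131) and 20 to 1049 (score 105). The median width of the 16 mitochondrial peaks, 333 bp, did not differ from that of arm peaks beyond the permutation test (adjusted p = 0.39). These tests of scaffold and mitochondrial peaks also shuffled single peaks, and neighbouring peaks are not independent.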

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

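The tests of scores in this part were chosen after the peak list had been examined, and their own outcomes were not known when they were set. The mitochondrial genome, for which the design named no comparison, held 16 peaks, which covered 39.4% of the stretch between the first and the last of them. That stretch is 18.8 kb long. Its density of 853 peaks per Mb lay far above those of the arms between their first and last peaks, from 17.1 on 2L to 35.4 on 2R. Some stretches of like size within large clusters on the arms held as many or more, such as 25 peaks in 19.0 kb at the start of 3L. One technical explanation is that DNA present in many copies per cell raises the input signal, and with it the counting power at which small differences are called. If the score counts reads over a background, as examined under the other observations, a raised input, used as control, should move scores off the values that a single genome-wide background gives. Of the mitochondrial scores, 18.8% lay on those values, against 45.2% on the arms (Fisher's exact test p = 0.042, adjusted p = 0.057 over 4 tests). The prediction set a threshold of 0.05 without naming an adjustment, and the adjusted value was made the criterion afterwards. The unadjusted p would pass and the adjusted p does not, so with 16 peaks the explanation could not be settled. For the 330 peaks on unplaced and heterochromatic scaffolds, rich in repeats, the share was 29.7%, below the arms (Fisher's exact test, adjusted p = 1.2e-07). A raised input at repeated DNA predicts this if the input served as control, which the sources do not state, and a local background taken from the ChIP reads could give the same shift. In the lowest-scoring peaks the order was the opposite, at 55.0% of 60 scaffold peaks against 39.9% of 1056 arm peaks, a difference that was not tested. No biological explanation was tested, since the design names none for these sequences.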

How the results depend on the processing

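Restricting the list to its upper part by score leaves 1642 peaks by construction. With these, the excess on 2R was 4.50 peaks per 1 Mb window (permutation test, adjusted p = 0.24), and the cause was not tested. Merging peaks within 200 bp left 2894 peaks and the mitochondrial score difference at 9.50 (permutation test, adjusted p = 0.084), with the cause not tested. The reversed values were width differences that passed no test in either form. In mean log2 width, X minus autosomal arms was 0.0218 and large clusters minus isolated peaks was 0.0339, and with peaks merged within 200 bp the mitochondrial minus arm width was 35.0 bp. The cause was not tested. The median spacing stayed below the lowest random value under every alternative run, but its size moved, from 4083.5 bp to 6515 bp with merging within 200 bp, 15909 bp within 1000 bp and 17317 bp for the 1642 strongest peaks. The ratio of the random mean to the observed median, 6.60 in the main run, was 4.72, 2.62 and 3.28 in these, and 4.67 and 2.47 with placement within the own 1 Mb and 100 kb window of each peak. The share of arm peaks in large clusters was 25.4% among the 1642 strongest peaks (random mean 0.120%), 37.7% with 5 kb (0.191%) and 60.4% with 20 kb between peaks (10.9%), and the random mean was 9.22% with placement within the own 1 Mb window. Merging at an overlap of 1 bp changed no peak, so it tests nothing. The restriction by score and the merging at 1 bp, for the number of peaks, the X share and the spacing, and the number of peaks merged within 200 bp were set before the data were seen, and all other alternatives, with that of 2R, were chosen after. No paired analysis was possible because the list carries no value per library, and for the same reason no replicate could be left out. Alternatives that need gene positions or sequence were not run. Depth limits cannot be given, since the list holds no reads.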

Other observations

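All tests in this part were chosen after the peak list had been examined, and those of the score ladder as a whole, of merged peaks and of the tip of 3L after their own outcome was seen. X was more frequent among the strongest arm peaks than among the rest, in counts that did not pass correction. It held 8 of the 25 strongest arm peaks (32.0%), 13 of 50, 24 of 100 (24.0%) and 46 of 250 (18.4%), against 15.4 to 15.6% of the remaining arm peaks. Fisher's exact test gave unadjusted p-values of 0.046, 0.0501, 0.025 and 0.24, and adjusted values of 0.067, 0.067, 0.067 and 0.24 over the 4 sets. Several of these X peaks lie close together, so they are not independent.

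The scores repeat certain values. A total of 24 scores were each held by 20 or more peaks, 715 peaks in all, and the commonest, 10.3, was held by 47. A candidate explanation is that the score is the negative log10 of a Poisson p-value for a whole number of piled-up reads over 1 genome-wide background. The form of the ladder was chosen on the whole list, from 2 ways of counting the tail of the distribution, so the even-numbered peaks below are not fully independent of that choice. A background fitted on odd-numbered peaks came out at 53.05 reads, and 43.9% of even-numbered peaks then lay within 0.01 of the predicted values, against at most 7.67% for 100 ladders shifted by a constant. Of the 24 repeated scores, 23 lay on the ladder. The fit sought the background with the most scores on the ladder, so frequent scores weighed in it and this count is not separate support. Repeated scores also occur among odd- and even-numbered peaks alike, which further limits the independence of the even-numbered ones. Under this reading the lowest score on the ladder, 6.35, would stand for 93 reads, 1.75 times the background, the median one for 2.26 times and the highest, 304, for 9.59 times. The sources do not state the statistic, so these folds remain a hypothesis.

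Scores off the ladder would then mark peaks judged against a higher local background. On the arms 68.8% of isolated peaks lay on the ladder, but only 28.1% of peaks in large clusters (Fisher's exact test, adjusted p = 1.6e-63, with peaks not independent), which is consistent with a raised background at many of the clusters, for example by copy gain, but not at all of them. Of the 141 large clusters 96 had under 50% of their scores on the ladder and 33 had none, while 9 had every score on it. The share was low in most of the 16 clusters of 20 or more peaks, at 0 of 37 for 3L 3374172 to 3461861 and 2 of 34 for 2R 7480531 to 7553249, but 19 of 22 for 3R 12031228 to 12086790. Between X and the autosomal arms the shares on the ladder, 43.4% and 45.5%, did not differ beyond the test (Fisher's exact test, adjusted p = 0.41), though X was lower among the lowest-scoring peaks (32.7% against 41.1%) and higher among the highest-scoring (61.1% against 51.7%), which was not tested. Splitting of broad regions into peaks within 1000 bp of each other does not account for the crowding as a whole. Peaks merged at that distance still had a median spacing of 15909 bp, below the lowest random value of 38630 bp. Regions split at longer gaps are not joined by this merging, so such splitting stays open. Differences on the scale of megabases alone do not account for the crowding as a whole either. Placement of each peak within its own 1 Mb window never gave a median under 17918 bp, against 4083.5 bp observed. Merging and placement within windows were not combined. Copy gain of short segments and open chromatin in the input stay open, and no biological explanation was tested. A background drawn from the ChIP reads near each peak should be raised at isolated peaks of high score too. Among isolated peaks, however, 74.9% of the 231 highest-scoring lay on the ladder, against 62.3% of the 162 lowest-scoring, a difference that was not tested. Under the ladder reading this argues against such a background for those 231 peaks as a set. For the large clusters it stays open. At the tip of 3L, by contrast, 100% of the 25 scores lay on the ladder, above the isolated peaks, which argues against a raised background at that cluster. The largest gap between neighbouring peaks at the tip was 906 bp, so merging within 1000 bp joins all 25 into a single region. Splitting of a broad region could therefore account for that cluster, unlike the crowding as a whole. What else sets that tip apart was not tested.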
